A study of Mus musculus with 4 samples.

How the data were processed

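Inguinal white adipose tissue of C57BL/6N mice aged 6 months was used, per the labels, with 2 libraries labelled wild type and 2 labelled PTRF knockout. Nuclei were captured with a Singleron GEXSCOPE nucleus kit and sequenced on an Illumina NovaSeq with paired-end 150 bp reads, per the labels' protocols. Per the submitters' processing notes, reads were counted against GRCm38 (mm10) and the nuclei were handled with Seurat 4.3.0. The aligner and its version are not given in the sources used here. The deposited files hold raw UMI counts per gene and barcode, and the submitters had limited them to barcodes of at least 500 UMIs before deposit, as the lowest total in the files is 500. No deposited expression value was changed by scaling here before the count tests. All columns of the files were used.

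The files list 53715 genes, of which 118 symbols occur more than 1 time, and 53620 gene identifiers occur in the annotation used here for coordinates (GENCODE M21). Tests were run on gene identifiers, and symbols are used for naming only. Of the fixed lists, Coasy and Bcl11b are not among the symbols of the files, Trarg1 was read as Tusc5 and Ccn2 as Ctgf. Strain is the same for both groups per the labels. Xist stood at 912, 638, 714 and 1059 CPM in the libraries labelled wild type 1 and 2 and knockout 1 and 2, and Uty at 2.49, 6.73, 5.62 and 4.40. Counts of Eif2s3y were 0 in each library, and those of Kdm5d were 2, 1, 0 and 4. The titles name a separate mouse for each library, and whether wild type 1 was handled with knockout 1 is not stated.

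Genotype groups, tests, gene lists, cell type markers, nucleus filters, the rule for naming genes and most alternatives were fixed before the data were examined. Later choices were the rule that a cluster takes the name of a cell type when at least 3 of its markers are among the 100 leading genes, the comparison of clusters by number, the separate adjustment of marker lists from gene lists, the glucocorticoid list, and 6 kinds of added alternatives: removal of the 5% of nuclei with the highest doublet scores, analysis without cluster 0 or without cluster 6, progenitors of cluster 4 only, vascular nuclei without those scored lymphatic, and both list families adjusted together. The last changed the number of lists called from 12 to 10 in all nuclei, from 7 to 6 in adipocytes and left it at 7 in progenitors.

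Barcodes were kept with at least 500 UMIs, at least 300 genes and at most 10% of UMIs from mitochondrially encoded genes. This removed 397, 161, 464 and 250 barcodes for mitochondrial share and 8, 6, 8 and 4 for genes, in the same order of libraries. Scrublet, run per library through scanpy, called 10, 1, 0 and 2 doublets, under 0.5% in each library, so doublet removal has not worked and doublets remain. Counts per 10000 on the log scale, 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 gave the clusters, without batch integration and without the labels. A class holds all nuclei of the clusters named for it. Classes and clusters with at least 50 nuclei in every library were compared, 13 in all, and no nucleus was treated as a replicate. Leading genes that define a cluster are not results of the comparison of that cluster.

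Counts were summed per library over all nuclei or over the nuclei of a class. Genes were filtered with filterByExpr, scaled with TMM and tested with the edgeR quasi-likelihood F test (glmQLFit with robust = TRUE), two-sided, adjusted by Benjamini-Hochberg (BH) over the genes tested in that comparison, with a threshold of 0.05. Adjusted p-values of genes come from this fit unless another tool is named. Levels are TMM-normalised CPM as mean ± SD over 2 libraries, and the SE of a log2 difference is its absolute value divided by the square root of F. The difference between adipocytes and progenitors was tested as the interaction of class and label on 8 sums, with the library as a block. Gene-by-gene differences with other scaling (DESeq2 size factors) moved the median of all genes by less than 0.1 in each comparison.

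Gene lists were tested with camera (limma) on voom values with a preset correlation of 0.01, BH over the lists with at least 5 tested members, and again with an estimated correlation and with fry, two-sided. With an estimated correlation and with fry 0 gene lists were called in all nuclei, adipocytes or progenitors, against 12, 7 and 7 by camera with the preset. The 21 lists are caveola components, Cavin1 neighbours on chromosome 11, lipogenesis and triglyceride synthesis, lipolysis and lipid droplet, thermogenic, fatty acid oxidation, adipocyte identity and adipokines, insulin signalling, extracellular matrix and fibrosis, inflammation, lipid-associated macrophage, perivascular macrophage, progenitor of the interstitial type, committed preadipocyte, hypoxia and angiogenesis, Pol I transcription and ribosome biogenesis, p53 and senescence, immediate early and heat shock, mitochondrially encoded, ribosomal proteins and nuclear-encoded oxidative phosphorylation. Marker lists of the cell types form a separate family. A list call with the preset correlation ranks its members against other genes and does not let the members move together.

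Class shares were compared with a two-sided exact permutation test over libraries, where 2 against 2 gives no p below 0.333. Within a label the gene counts of the replicate libraries differed more than counting allows (chi-square per degree of freedom 38.7 for the label wild type and 57.9 for knockout). Named genes were, in all nuclei, adipocytes and progenitors, the 12 largest differences up and the 12 down among called genes with a mean of at least 10 CPM and no overlap between groups, and 4 each way in other classes, together with the caveola components and up to 4 members of each list with the smallest p. Predicted genes were counted and named only where fewer than 5 others passed. Some genes that pass this rule are counted but not reported here by name. Gm47283 is named throughout, a choice made after its values were seen.

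As a test of the method, 200 genes were changed by 2 or 4 times in counts simulated for each comparison, with dispersions from a fit without groups. Such a fit counts differences between the groups as spread, so its setting is not that of the reported tests. With the dispersion of each gene, 57.6% of genes changed 4 times were called over all nuclei, 30.2% in adipocytes, 50.5% in progenitors and 46.9% in vascular nuclei, none in the wrong direction, and 4.08%, 0%, 2.11% and 2.33% of genes changed 2 times. The share of false calls among calls was 19.7%, 9.38%, 16.1% and 13.0% there, above the threshold of 5% that BH aims at, and 6.06%, 2.17%, 0% and 9.84% with the trend of the dispersion. A gene without a call may therefore have changed.

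Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, scikit-learn 1.9.0 and matplotlib 3.10.9, R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and BLAST 2.17.0. The seed was 0.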

Results

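Nuclei of inguinal white adipose tissue, the subcutaneous fat pad of the groin, were profiled by single-nucleus RNA sequencing in C57BL/6N mice aged 6 months. Of the 4 libraries, 2 are labelled wild type and 2 are labelled PTRF knockout, and the titles name a separate mouse for each. PTRF is an older name of cavin-1, the coat protein of caveolae (small pits of the plasma membrane that are dense in adipocytes), encoded by Cavin1. The files held 15928 and 6827 barcodes for the libraries labelled wild type 1 and 2, and 12454 and 16141 for those labelled knockout 1 and 2. After filtering, 15518, 6663, 11988 and 15885 nuclei remained in the same order, with median UMIs of 1022, 933, 844.5 and 1400 and median genes of 642, 581, 543 and 863. Clustering gave 22 clusters. Of these, 14 were named for 11 cell types by their markers and 8 are given by number. A class name, such as adipocyte, means nuclei resembling that type by markers alone. Every difference is the group labelled knockout minus the group labelled wild type, on the log2 scale with its standard error (SE), and n = 2 libraries per group.

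Cavin1 goes against the labels. In all nuclei it stood at 1.48 ± 0.769 normalised CPM (mean ± SD, n = 2) in the libraries labelled wild type and 52.6 ± 6.70 in those labelled knockout, a log2 difference of 5.08 (SE 0.54, adjusted p = 1.09e-16). The raw counts were 40 and 9 against 730 and 1759. Adipocyte nuclei gave 2.44 ± 1.70 against 95.5 ± 6.09 CPM (log2 5.05, SE 0.50, adjusted p = 2.89e-10). Cavin1 was also called, in the same direction, in progenitors (5.10, SE 0.56), vascular endothelial nuclei (6.98, SE 0.91) and cluster 0 (4.81, SE 0.47). The names of all 4 deposited files carry the genotype opposite to the sample label. Which part of the gene the knockout removes is not given in the sources used here, and the groups are kept as labelled throughout. The words higher and lower therefore refer to labels that Cavin1 contradicts: the group labelled knockout is the group rich in Cavin1.

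**Figure D1:**
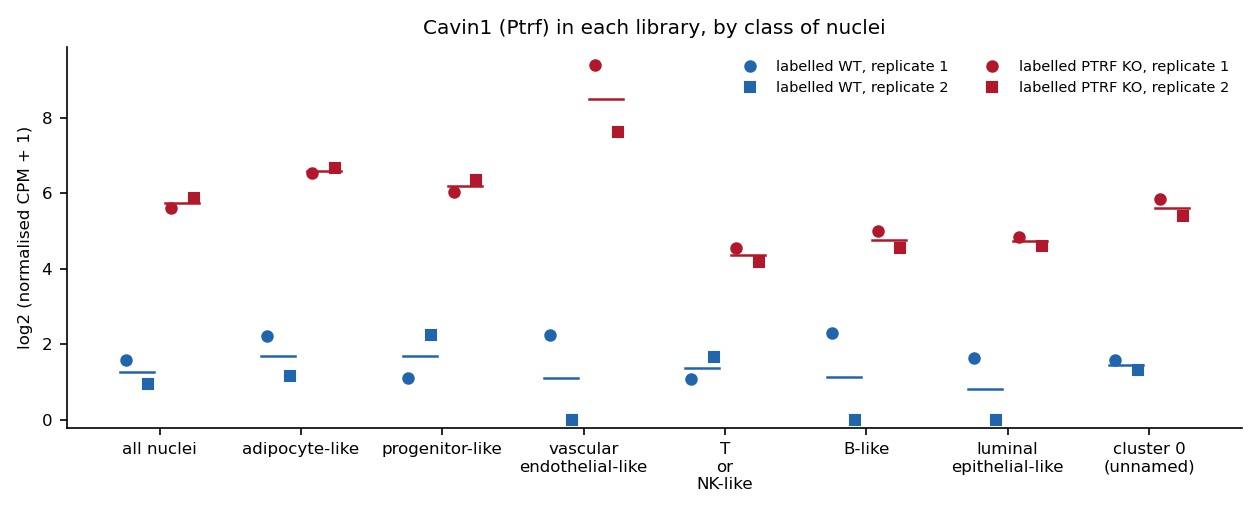
Cavin1 in each library by class, as log2 of normalised CPM plus 1. Circles are replicate 1, squares replicate 2, and bars the group means.

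The remaining caveola components did not pass in any class. The list of caveola components holds Cavin1 itself and was not tested without it in any class or cluster. A call of this list therefore does not show that the other components rose as a set. In adipocytes Cav1 (0.70), Cavin2 (0.59), Cav2 (0.81), Ehd2 (0.42) and Cavin3 (2.21, adjusted p = 0.347) all had log2 differences above 0 without a call. The list of caveola components was called higher in all nuclei (7 of 11 members above 0, median 0.41, adjusted p = 1.05e-06, and adjusted p = 0.562 with an estimated correlation), where only Cavin1 rose, also when adjusted over the list alone. It was higher in adipocytes too (7 of 10 above 0, adjusted p = 9.4e-04, and adjusted p = 0.571 with an estimated correlation), with 1 member called over all genes and 2 adjusted over the list alone. In both, the call of this list was absent without the library labelled knockout 2 (adjusted p = 0.211 and 0.237).

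Over all nuclei, transcripts of IgA-secreting cells and some single adipocyte genes were higher in the group labelled knockout, which is the group rich in Cavin1. The heavy chain gene Igha (log2 6.60, SE 0.62, adjusted p = 1.25e-21) and Jchain (4.22, SE 0.51), whose product joins IgA units, rose. So did Ido1 (2.94, SE 0.48; tryptophan breakdown), Npr3 (2.48, SE 0.48; clearance of natriuretic peptides), Adrb3 (2.12, SE 0.51, adjusted p = 0.0332; the β-adrenergic receptor that drives lipolysis in mouse fat), Pnpla3 (2.01, SE 0.48; a lipid-droplet enzyme) and Lep (2.03, SE 0.46; leptin). Falling genes included the transcription factor gene Irf4 (-2.78, SE 0.49, adjusted p = 6.88e-05), the metallothionein gene Mt2 (-2.36, SE 0.48) and Rgs2 (-1.91, SE 0.46), which restrains G-protein signalling. Igha and Jchain lead the plasma cluster, Ido1 the luminal cluster and Lum (2.00, SE 0.46) a progenitor cluster. Sums over all nuclei use no clusters but follow the mix of nuclei. Plasma nuclei numbered 25 and 9 in the libraries labelled wild type and 181 and 577 in those labelled knockout. Luminal nuclei went against Ido1, at 3.46 ± 0.499% and 2.27 ± 0.196% in the same order of groups.

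In total edgeR called 29 of 28074 genes over all nuclei, 20 higher and 9 lower, and 9 of the 29 are predicted genes. With the classes at equal shares (limma) 4 genes were called, 4 higher and 0 lower. With at least 1000 UMIs and 500 genes per nucleus it was 3 higher and 0 lower, so every lower call ended in both. Adrb3 went from 62.5 ± 32.0 to 272 ± 104 CPM, Lep from 12.1 ± 6.81 to 49.1 ± 35.0 and Mt2 from 30.4 ± 17.6 to 5.84 ± 4.09. Glb1l2, a galactosidase-like gene, was higher by 2.75 (SE 0.47, adjusted p = 2.68e-05) and Cd1d1, which presents lipid antigens, by 2.20 (SE 0.46). Only Cavin1 and Igha among the 16 named genes kept the call whichever library was left out: Ido1 (2.36) lost it without labelled wild type 1, Jchain (2.47) without labelled knockout 2, and Irf4 was -0.93 without labelled wild type 1. Adrb3 (1.61 to 2.78), Lep (1.01 to 2.69), Pnpla3 (1.33 to 2.47), Cd1d1 (1.22 to 2.76), Lum (0.96 to 2.59) and Rgs2 (-1.44 to -2.32) lost the call with any library left out, lowest without labelled knockout 2 for Lep, Pnpla3, Cd1d1 and Lum, without labelled wild type 2 for Adrb3 and without labelled wild type 1 for Rgs2 in size. Npr3 and Glb1l2 kept it only without labelled knockout 1 (2.98 and 3.34) and Mt2 only without labelled wild type 2 (-2.91). The number called was 13, 18, 12 and 5 without labelled wild type 1, wild type 2, knockout 1 and knockout 2, and of all genes tested 14.9% had no overlap between the groups where chance alone gives 33.3%.

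Gene lists put lipid synthesis first over all nuclei. Lipogenesis and triglyceride synthesis was higher (21 of 25 members above 0, median 0.46, adjusted p = 1.48e-12, and adjusted p = 0.562 with an estimated correlation), with 1 member called over all genes (Pnpla3) and 5 adjusted over the list alone. Lipolysis and lipid droplet (15 of 23, adjusted p = 1.05e-06), adipocyte identity and adipokines (13 of 17, adjusted p = 1.87e-09), extracellular matrix and fibrosis (24 of 29, adjusted p = 9.81e-08), committed preadipocyte (9 of 11, adjusted p = 0.00233) and ribosomal proteins (22 of 24, adjusted p = 1.87e-09) were also higher. Members called over all genes were Adrb3 for lipolysis, 2 for identity, and 0 for the other 3. Counts adjusted over the list alone were 3 higher for lipolysis, 4 higher and 1 lower for identity, 1 for matrix, 3 higher and 1 lower for committed preadipocyte, and 0 for ribosomal proteins. Lower were the interstitial progenitor list (3 of 9 above 0, adjusted p = 8.64e-04), p53 and senescence (3 of 13, adjusted p = 8.53e-04), immediate early and heat shock (5 of 18, adjusted p = 0.00134), and the thermogenic list (5 of 19, adjusted p = 0.0409). None of their members was called, and 1 p53 member was lower when adjusted over the list alone. Lipid-associated macrophage was called higher (adjusted p = 0.0409) although its median (-0.05) and mean (-0.03) lie below 0. Every list of this paragraph had adjusted p = 0.562 with an estimated correlation, except the thermogenic list with adjusted p = 0.623 with an estimated correlation.

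Markers of adipocytes (10 of 12 above 0, adjusted p = 9.5e-19, and adjusted p = 0.577 with an estimated correlation) and of B cells (9 of 9, adjusted p = 2.35e-14, and adjusted p = 0.577 with an estimated correlation) moved up with these lists over all nuclei. Leaving out labelled wild type 2 or labelled knockout 2 ended the calls of lipogenesis (adjusted p = 0.377 and 0.211), lipolysis (0.343 and 0.663), identity (0.343 and 0.663), committed preadipocyte (0.928 and 0.33), ribosomal proteins (0.343 and 0.663) and the thermogenic list (0.776 and 0.669). The matrix list was called lower without labelled knockout 2 (adjusted p = 0.0452). Without labelled wild type 1 the calls of immediate early genes (0.553) and p53 (0.867) ended. Without labelled knockout 1 it was those of immediate early genes (0.149), p53 (0.615), lipid-associated macrophage (0.0548) and the interstitial list (0.462). Lipid-associated macrophage was called lower without labelled wild type 2 (0.0452) and not called without labelled knockout 2 (0.443), and the interstitial list was not called without labelled wild type 2 (0.286).

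Adipocyte nuclei differed in single genes of several functions. In the group labelled knockout, rich in Cavin1, Adrb3 rose (log2 1.98, SE 0.47, adjusted p = 0.0299; 220 ± 56.3 to 873 ± 155 CPM). The metallothionein genes Mt1 (-2.72, SE 0.42) and Mt2 (-3.56, SE 0.46, adjusted p = 1.58e-06), and the glucocorticoid-induced co-chaperone gene Fkbp5 (-2.55, SE 0.56, adjusted p = 0.0264, from 1280 ± 416 to 218 ± 202) fell. So did Pdk4 (-1.66, SE 0.38), which restrains glucose oxidation. The secreted matrix gene Thbs1 fell from 75.2 ± 2.86 to 6.05 ± 0.525 CPM (-3.62, SE 0.44, adjusted p = 1.36e-07). Npr3 (2.56, SE 0.45, adjusted p = 6.09e-04), the adhesion gene Ncam2 (2.53, SE 0.43) and Pnpla3 (1.82, SE 0.45, adjusted p = 0.0397) rose. Of these genes only Thbs1 and Mt2 kept the call without labelled wild type 1, where Adrb3 was 2.28, Mt1 -2.44, Fkbp5 -2.16, Pdk4 -1.74, Npr3 2.05, Ncam2 2.21 and Pnpla3 1.46. Without labelled wild type 2 the calls of Adrb3 (1.73), Fkbp5 (-2.84), Pdk4 (-1.60), Npr3 (3.28), Ncam2 (2.88) and Pnpla3 (2.29) ended, without labelled knockout 1 that of Fkbp5 (-1.80; -4.09 without labelled knockout 2), and without labelled knockout 2 those of Pdk4 (-1.58) and Pnpla3 (1.35).

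In adipocytes 64 of 17559 genes were called, 31 higher and 33 lower, 6 of them predicted. Signalling genes among those lower were Rgs2 (-3.16, SE 0.47), the G-protein subunit gene Gnal (-2.35, SE 0.41, adjusted p = 3.52e-04), the immediate early gene Fosb (-4.20, SE 0.76) and Irf4 (-3.63, SE 0.62, adjusted p = 0.0135; 468 ± 458 to 38.1 ± 4.68 CPM). Fam129b, a survival gene, fell from 155 ± 4.28 to 24.0 ± 1.07 (-2.69, SE 0.40). Glb1l2 (3.11, SE 0.44, adjusted p = 9.6e-06) and Cd1d1 (2.10, SE 0.42, adjusted p = 0.0045) rose. Olfr732 (2.54) and Olfr731 (2.23), neighbouring paralogs on chromosome 14, were called higher as well, an uncertain pair because reads can be shared between them. Igha (5.24, SE 0.77), a plasma-cell gene, was also called higher inside the adipocyte class. Whether doublets or free plasma-cell RNA account for Igha here, or in B and T or NK nuclei, was not tested. Cavin1, Thbs1, Mt2 and Fam129b were the genes named here that kept the call with each library left out. Without labelled wild type 1 the count was 9, Irf4 (-1.92), Rgs2 (-1.95), Gnal (-1.97), Glb1l2 (2.90), Cd1d1 (2.10), Igha (5.12) and both Olfr genes (Olfr731 at 3.76) lost the call and Fosb was untested. The count was 25 without labelled wild type 2, where Glb1l2 (3.31), Cd1d1 (2.10) and both Olfr genes lost it, and 178 without labelled knockout 1, and Cd1d1 (1.25), Igha (3.90) and Olfr731 (1.98) lost it without labelled knockout 2.

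**Figure D2:**
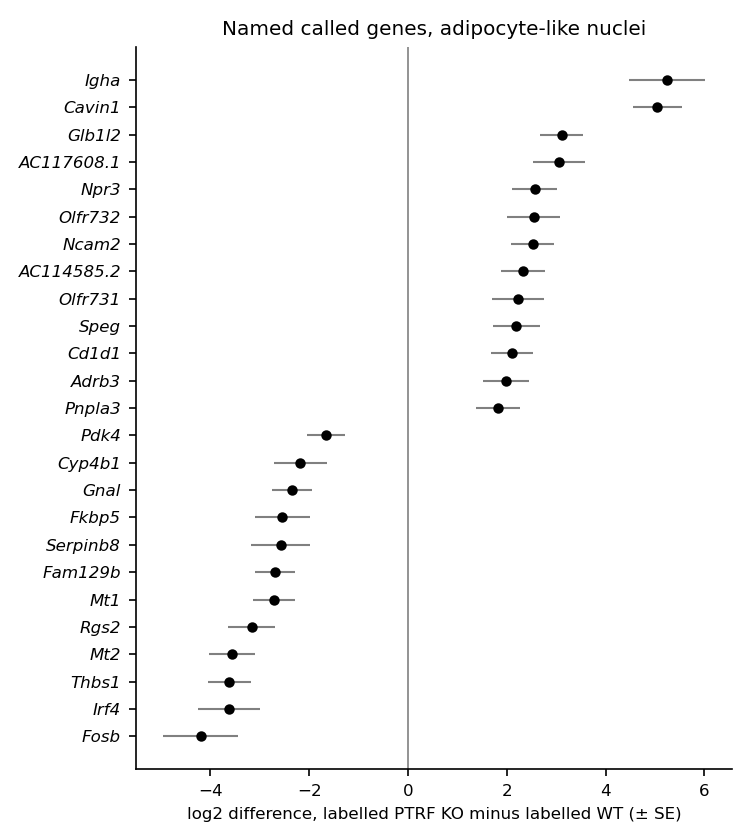
Log2 difference ± SE of 25 named genes called in adipocyte nuclei, labelled knockout minus labelled wild type.

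Immediate early and heat shock was the list called most strongly in adipocytes, and it was lower (3 of 14 members above 0, median -0.61, adjusted p = 5.26e-07, and adjusted p = 0.571 with an estimated correlation). Of its members Fosb fell, with 3 lower when adjusted over the list alone. Lipogenesis was higher (17 of 25 above 0, adjusted p = 4.24e-06, and adjusted p = 0.571 with an estimated correlation) through Pnpla3, and through 7 higher and 2 lower members adjusted over the list alone. Lipolysis was higher (16 of 21, adjusted p = 0.0223, and adjusted p = 0.676 with an estimated correlation) with 1 member called up (Adrb3) and 1 down, and 2 up and 1 down adjusted over the list alone. Adipocyte identity was higher (12 of 17, adjusted p = 0.0237, and adjusted p = 0.676 with an estimated correlation), with 1 member called and 3 adjusted over the list alone. The thermogenic list was lower (5 of 18 above 0, adjusted p = 0.0104, and adjusted p = 0.676 with an estimated correlation), with 0 called over all genes and 1 down adjusted over the list alone. The perivascular macrophage list was called higher (5 of 6, adjusted p = 0.0448, and adjusted p = 0.571 with an estimated correlation) with 0 members called.

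Adipocyte markers (10 of 12 above 0, adjusted p = 2.39e-07, and adjusted p = 0.793 with an estimated correlation) and fibroblast markers (11 of 12, adjusted p = 3.11e-05, and adjusted p = 0.793 with an estimated correlation) were higher in the adipocyte class beside these lists. Without labelled knockout 2 the calls of lipogenesis (adjusted p = 0.2), lipolysis (0.424), thermogenic (0.253), identity (0.424) and immediate early genes (0.2) ended. Without labelled wild type 2 those of lipolysis (0.757), thermogenic (0.838) and identity (0.0795) ended, and the perivascular list was not called without labelled wild type 1 (0.893) or labelled knockout 1 (0.435).

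**Figure D3:**
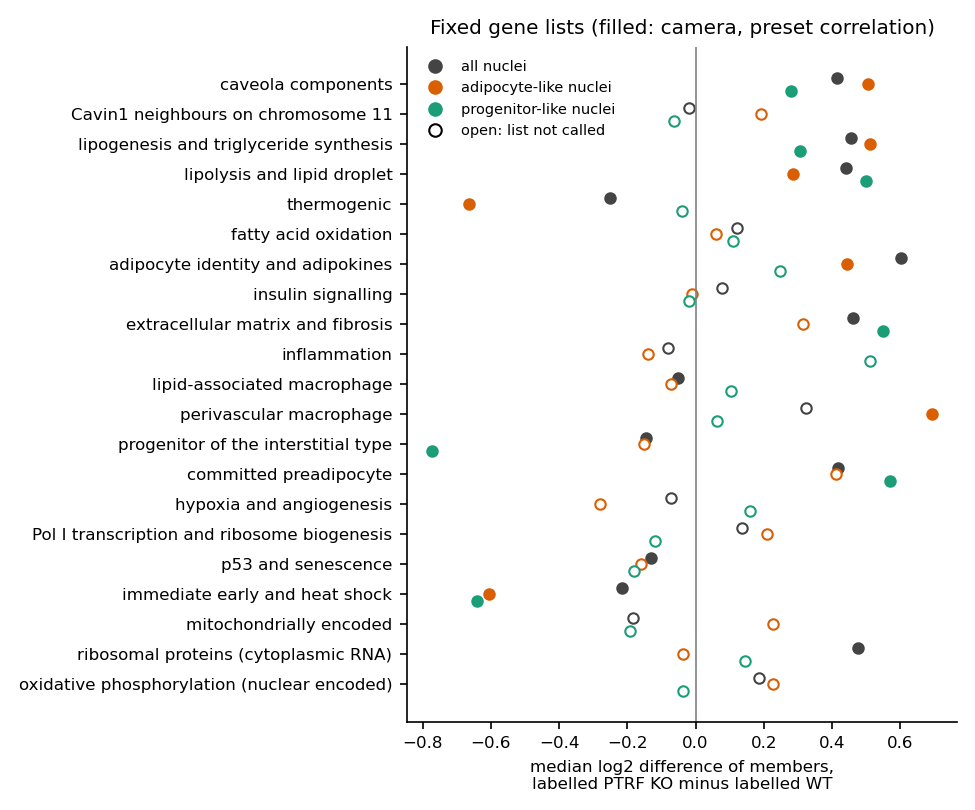
Median log2 difference of each of 21 gene lists in all nuclei, adipocytes and progenitors. Filled points were called by camera with its preset correlation.

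Uncalled lists in adipocytes were fatty acid oxidation (adjusted p = 0.217; median 0.06, mean -0.17, with Pdk4 lower), insulin signalling (0.536), extracellular matrix (0.0964, with Thbs1 lower), inflammation (0.0768), committed preadipocyte (0.0558), hypoxia (0.587) and Pol I transcription and ribosome biogenesis (0.217). So were p53 (0.151), mitochondrially encoded genes (0.0558), nuclear-encoded oxidative phosphorylation (0.0558), and the interstitial progenitor, lipid-associated macrophage and ribosomal protein lists (0.711 each). Genes beside Cavin1 on chromosome 11 were not called as a list in adipocytes (0.587), progenitors (0.94) or all nuclei (0.79). Over all nuclei, fatty acid oxidation (0.62), insulin signalling (0.569), inflammation (0.62), perivascular macrophage (0.13), hypoxia (0.22), Pol I (0.192), mitochondrially encoded (0.0787) and oxidative phosphorylation (0.0841) were uncalled. In progenitors the uncalled lists were thermogenic (0.9), fatty acid oxidation (0.9), identity (0.246), insulin signalling (0.834), inflammation (0.721), lipid-associated macrophage (0.509), perivascular macrophage (0.514), hypoxia (0.342), Pol I (0.246), p53 (0.569), mitochondrially encoded (0.509), ribosomal proteins (0.0989) and oxidative phosphorylation (0.952).

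Progenitor nuclei differed in few genes. Besides Cavin1, the muscarinic receptor gene Chrm2 rose (log2 2.80, SE 0.39, adjusted p = 0.0288; 14.6 ± 2.31 to 98.7 ± 32.7 CPM) and so did Lum, which encodes a collagen-binding proteoglycan (2.05, SE 0.29, adjusted p = 0.0288; 87.1 ± 2.94 to 360 ± 66.4). The complement gene C7 fell (-3.02, SE 0.40, adjusted p = 0.0222; 121 ± 54.4 to 15 ± 0.111), as did Irf4 (-2.82, SE 0.37, adjusted p = 0.0222; 101 ± 4.96 to 13.1 ± 4.97). These directions are of labels that Cavin1 contradicts, and 6 of 12539 genes were called, 4 higher and 2 lower. Lum leads progenitor cluster 4 and C7 leads cluster 16, so neither is read as a result independent of clustering. Without labelled knockout 2, Chrm2 (2.37), Lum (1.82), C7 (-3.03) and Irf4 (-3.40) lost the call, and the number called was 81, 57 and 60 without labelled wild type 1, wild type 2 and knockout 1. Within cluster 4 alone Chrm2 (2.77, adjusted p = 0.182), Lum (1.77, adjusted p = 0.182) and Irf4 (-3.07, adjusted p = 0.613) were not called, while C7 was (-3.53, adjusted p = 0.0117).

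Genes of committed preadipocytes were higher in progenitors of the group labelled knockout, rich in Cavin1 (10 of 11 above 0, adjusted p = 1.92e-05, and adjusted p = 0.471 with an estimated correlation). Of these 0 were called over all genes, and 3 up and 1 down adjusted over the list alone. Interstitial progenitor genes were lower (0 of 9 above 0, median -0.77, adjusted p = 3.11e-06, and adjusted p = 0.659 with an estimated correlation; 0 called, 1 down adjusted over the list alone). Clusters 4 and 10 hold the class in different proportions: cluster 10, led by the interstitial gene Pi16, made up 35.4% and 38.3% of progenitor nuclei in the libraries labelled wild type and 11.1% and 29.1% in those labelled knockout. Within cluster 4 the interstitial list turned to higher (7 of 9 above 0, adjusted p = 0.00342, and adjusted p = 0.725 with an estimated correlation), and the committed preadipocyte list was not called.

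Immediate early genes were lower in progenitors (1 of 10 above 0, median -0.64, adjusted p = 1.48e-07, and adjusted p = 0.471 with an estimated correlation), with 0 called and 2 down adjusted over the list alone. This held within cluster 4 (2 of 10, adjusted p = 4.98e-07, and adjusted p = 0.725 with an estimated correlation). Extracellular matrix genes were higher (22 of 28, adjusted p = 4.74e-07, and adjusted p = 0.471 with an estimated correlation; 0 called, 3 up and 1 down adjusted over the list alone). Lipolysis was higher (16 of 18, adjusted p = 5.48e-05, and adjusted p = 0.762 with an estimated correlation), with 0 called and 1 adjusted over the list alone. Lipogenesis was higher (14 of 22, adjusted p = 0.00761, and adjusted p = 0.659 with an estimated correlation), with 0 called by either adjustment. Caveola components were higher (6 of 7, adjusted p = 0.00761, and adjusted p = 0.471 with an estimated correlation), with Cavin1 alone called. So were adipocyte markers (10 of 11, adjusted p = 1.09e-04, and adjusted p = 0.575 with an estimated correlation) and macrophage markers (4 of 5, adjusted p = 0.0108, and adjusted p = 0.575 with an estimated correlation). Without labelled knockout 2, matrix (adjusted p = 0.199), lipolysis (0.909), lipogenesis (0.932) and caveola components (0.263) lost the call. Lipolysis and lipogenesis also lost it without labelled wild type 2 (0.224 each), caveola components without labelled wild type 1 (0.24), and within cluster 4 lipogenesis and caveola components were not called.

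Vascular endothelial nuclei of the group labelled knockout, rich in Cavin1, had fewer lymphatic transcripts. Lymphatic markers were lower (0 of 6 above 0, median -2.16, 3 members called, adjusted p = 8.95e-07, and adjusted p = 0.202 with an estimated correlation), Prox1 (-1.50) and Mmrn1 (-2.37) among them, and Mmrn1 is also a leading gene of the cluster. The transcription factor gene Nfatc2 (-3.27, SE 0.53, adjusted p = 6.48e-05, from 248 ± 38.4 to 22.9 ± 6.56 CPM) and the matrix genes Tgfbi (-3.26, SE 0.58) and Col18a1 (-3.91, SE 0.72) fell. The scramblase gene Plscr2 (3.64, SE 0.86, adjusted p = 0.00818), Tmem182 (3.52, SE 0.85) and the guidance gene Slit2 (3.17, SE 0.81, adjusted p = 0.0177; a leading gene of progenitor cluster 4) rose. The class sums held only 316540 and 133979 UMIs in the libraries labelled wild type and 140431 and 498646 in those labelled knockout. Levels near 10 CPM therefore rest on few UMIs. In the libraries labelled wild type Plscr2 stood at 11.2 and 0 CPM, Tmem182 at 7.49 and 9.50 and Slit2 at 11.2 and 9.50. In those labelled knockout Col18a1 stood at 0 and 11.5 CPM and Tgfbi at 9.11 and 25.2. Called genes numbered 117 of 5002, 33 higher and 84 lower, and 40.2% of tested genes had no overlap between the groups (chance 33.3%). With the class set by marker score 3 of 10057 genes were called, 3 higher and 0 lower, so every lower call ended.

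Nuclei whose highest marker score was lymphatic made up 27.8% and 21.0% of vascular nuclei in the libraries labelled wild type (76 and 22 nuclei) and 3.57% and 7.25% in those labelled knockout (5 and 20). Without them 41 genes were called. Cavin1 (6.54), Plscr2 (7.40, adjusted p = 0.0118) and Nfatc2 (-3.26, adjusted p = 0.00287) kept the call, while Tmem182 (3.10), Slit2 (2.72) and Col18a1 (-4.65, adjusted p = 0.0529) lost it and Tgfbi was untested. Plscr2 (7.5 without labelled wild type 1) and Slit2 lost the call with any library left out, Col18a1 was -7.49 without labelled knockout 2, Tmem182 kept it only without labelled wild type 2, and Col18a1 (-3.71) and Tgfbi (-3.18) lost it without labelled wild type 1, where 59 genes were called, against 54 without labelled wild type 2.

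Adipocyte transcripts were higher in the vascular class. Lists outside all nuclei, adipocytes and progenitors were not tested with a library left out, here and in the classes and clusters below. Lipolysis was higher as a list (13 of 14 above 0, adjusted p = 3.85e-06, and adjusted p = 0.698 with an estimated correlation), with 2 members called and 7 adjusted over the list alone. Lipogenesis was higher (11 of 13, adjusted p = 0.0471, and adjusted p = 0.84 with an estimated correlation), with 1 called and 2 adjusted over the list alone. For identity (9 of 12 above 0, adjusted p = 0.0471, and adjusted p = 0.84 with an estimated correlation) the counts were 2 called, and 4 up and 1 down adjusted over the list alone. Committed preadipocyte was higher (7 of 8, adjusted p = 0.0245, and adjusted p = 0.698 with an estimated correlation), with 0 called and 2 adjusted over the list alone. Markers of adipocytes (10 of 10, 3 called, adjusted p = 6.77e-10, and adjusted p = 0.202 with an estimated correlation) and of fibroblasts (8 of 9, adjusted p = 0.0038, 1 called, and adjusted p = 0.202 with an estimated correlation) were called higher as lists. Without nuclei scored lymphatic, the calls of lipogenesis (adjusted p = 0.241), committed preadipocyte (0.241) and fibroblast markers (0.35) ended, while lipolysis and identity (0.00185 each, and adjusted p = 0.683 with an estimated correlation) and adipocyte markers (1.73e-08, and adjusted p = 0.241 with an estimated correlation) stayed called with the preset. Car3 (1.55), Cfd (1.79) and Cidec (1.91), genes of adipocyte type, were called higher, next to the endothelial receptor gene Flt1 (1.27). Whether doublets or free adipocyte RNA account for the adipocyte transcripts of the vascular class was not tested.

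The predicted gene Gm47283 was the most widespread call. It was called higher in 12 of 13 classes and clusters, not in luminal nuclei, with log2 differences of 4.3 to 6.64 over all 13. In macrophages it was the only gene called of 9146 (5.83, SE 0.56, adjusted p = 0.00119; DESeq2 also called 1). In B nuclei, 5 of 13268 genes were called. Igha (3.22, SE 0.71, adjusted p = 0.0175) and the mitochondrial gene mt-Nd3 (2.63, SE 0.53, adjusted p = 0.00421) rose, and the IgG1 heavy chain gene Ighg1 fell (-3.24, SE 0.66, adjusted p = 0.00421). In B nuclei mt-Nd3 stood at 2.95 and 51.3 CPM in labelled wild type 1 and 2, and at 145 and 111 in labelled knockout 1 and 2. In progenitors it stood at 0, 52.5, 44.0 and 56.7 CPM in the same order. Its low level in labelled wild type 1 was thus not particular to B nuclei. In T or NK nuclei, 6 of 14462 genes were called: Igha (4.95, SE 0.84) and Nnat (2.01, SE 0.46), an adipocyte cluster gene, rose, and the peptide transporter gene Slc15a2 (-2.90, SE 0.64, adjusted p = 0.0207) and Trnp1 (-2.26, SE 0.48) fell. Luminal epithelial nuclei had 0 of 10939 genes called by edgeR, with 348 at unadjusted p below 0.05, and 4 called by DESeq2. Leaving out labelled wild type 1 ended every named call of B nuclei (mt-Nd3 1.38, Ighg1 -1.51) and all but Gm47283 in T or NK nuclei (Slc15a2 -1.09, Trnp1 -1.04, Igha 8.92), and brought 436 calls in luminal nuclei. Without labelled wild type 2 luminal nuclei had 102, mt-Nd3 was 5.38, and the calls of Igha in B nuclei (3.00), Nnat (1.76) and Gm47283 in B (6.05) and T or NK nuclei (5.85) ended. Without labelled knockout 1 those of mt-Nd3 (2.46), Ighg1 (-3.23) and Trnp1 (-2.14) ended, and without labelled knockout 2 Igha in B nuclei was 1.54 and in T or NK nuclei 3.95, Ighg1 -3.23, Nnat 0.91, Slc15a2 -1.79 and Trnp1 -2.41, with no call.

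The mitochondrially encoded list was higher in B (8 of 8, adjusted p = 4.42e-12, and adjusted p = 0.536 with an estimated correlation) and T or NK nuclei (7 of 8, adjusted p = 9.56e-06, and adjusted p = 0.505 with an estimated correlation). It was lower in macrophages (0 of 8, median -0.78, adjusted p = 1.42e-04, and adjusted p = 0.679 with an estimated correlation). The median mitochondrial share of UMIs per nucleus was 1.68% and 1.04% in the libraries labelled wild type and 2.23% and 2.11% in those labelled knockout, and the list was not compared between classes. Macrophages were also higher in lipid-associated macrophage genes (7 of 9, adjusted p = 0.00229, and adjusted p = 0.679 with an estimated correlation), with 0 members called and 3 adjusted over the list alone. Lipolysis (adjusted p = 2.4e-04, and adjusted p = 0.679 with an estimated correlation), identity (1.42e-04, and adjusted p = 0.595 with an estimated correlation) and matrix genes (0.00124, and adjusted p = 0.595 with an estimated correlation) were higher in macrophages. Adipocyte markers were higher there too (9 of 10, adjusted p = 1.12e-07, and adjusted p = 0.268 with an estimated correlation). Whether doublets or free adipocyte RNA account for the lipid lists in macrophages was not tested. Ribosomal protein genes were higher in T or NK (22 of 24, adjusted p = 3.59e-15, and adjusted p = 0.505 with an estimated correlation), B (20 of 23, adjusted p = 1.51e-07, and adjusted p = 0.536 with an estimated correlation) and luminal nuclei (22 of 23, adjusted p = 6.69e-09, and adjusted p = 0.725 with an estimated correlation). None of their members was called.

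Lipid lists were higher in those 3 classes as well, each with the same estimated-correlation value as its ribosomal list. B nuclei gave lipolysis (adjusted p = 1.58e-05; 0 called, 4 adjusted over the list alone), identity (0.00108), matrix (6.94e-04) and lipogenesis (0.0377), with lipid-associated macrophage genes lower (0.038). T or NK nuclei gave lipolysis (4.8e-06; 0 called, 3 adjusted over the list alone), lipogenesis (3.31e-05), identity (0.0057; Nnat called), caveola components (0.00875), matrix (0.0118) and committed preadipocyte (0.0139). Luminal nuclei gave lipolysis (8.15e-04), matrix (0.00133) and lipogenesis (0.0156). Adipocyte markers were higher beside them in B (adjusted p = 1.32e-05, and adjusted p = 0.84 with an estimated correlation), T or NK (3.27e-12, and adjusted p = 0.26 with an estimated correlation) and luminal nuclei (0.0152, and adjusted p = 0.427 with an estimated correlation). Doublets remain in these classes, and whether doublets or free adipocyte RNA account for the lipid lists was not tested. The lipid lists are therefore not read as changes within B, T or NK or luminal cells.

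Cluster 0, 10900 nuclei of low depth without cell-type markers, had 20 of 20333 genes called, 14 higher and 6 lower. Adrb3 (2.03, SE 0.25, adjusted p = 8.42e-04; 40.9 ± 10.8 to 163 ± 24.2 CPM), the membrane receptor gene Mmd (2.22, SE 0.29, adjusted p = 0.00158) and the junction gene Amotl2 (1.86, SE 0.30, adjusted p = 0.0124) rose in the group labelled knockout, rich in Cavin1. Speer4cos fell (-2.58, SE 0.38, adjusted p = 0.008). Lipolysis was higher in cluster 0 (18 of 21, adjusted p = 4.91e-24, and adjusted p = 0.404 with an estimated correlation), with 3 members called and 9 adjusted over the list alone. Lipogenesis was higher (19 of 24, adjusted p = 1.56e-13, and adjusted p = 0.428 with an estimated correlation), with 1 called and 8 adjusted over the list alone. Caveola components, Cavin1 included, were higher (9 of 9, adjusted p = 2.31e-07, and adjusted p = 0.404 with an estimated correlation). Of these, 1 was called (Cavin1), and 2 adjusted over the list alone. Adipocyte markers were called higher as a list beside them (3 of 12 called, adjusted p = 9.63e-29, and adjusted p = 0.482 with an estimated correlation). In cluster 12, led by H2-M2 and Fscn1, the lipid-droplet gene Cidec (2.35, SE 0.41, adjusted p = 0.0313), Tenm4 (1.96, SE 0.36) and the ribosomal gene Rpsa (1.77, SE 0.29, adjusted p = 0.022) rose. Adipocyte markers were higher there (adjusted p = 1.22e-08, and adjusted p = 0.0584 with an estimated correlation). Cidec (2.27), Tenm4 (1.57) and Rpsa (1.45) lost the call without labelled wild type 2, Cidec (2.39) also without labelled wild type 1. Clusters 5, 7, 11 and 16 had only Gm47283 called.

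No class share was shown to differ. Adipocytes made up 15.1 ± 3.88% of nuclei in the group labelled wild type and 14.8 ± 0.0238% in that labelled knockout (exact permutation p = 1). Progenitors made up 8.91 ± 0.233% and 8.46 ± 3.80% and macrophages 3.81 ± 0.341% and 3.98 ± 2.15% (exact permutation p = 1 each). B nuclei were 7.99 ± 1.73% and 11.9 ± 3.24% and luminal nuclei 3.46 ± 0.499% and 2.27 ± 0.196%, each without overlap (exact permutation p = 0.333, the smallest that 2 against 2 libraries can give). Vascular nuclei were 1.67 ± 0.130% and 1.45 ± 0.403%, and T or NK nuclei 11.1 ± 4.46% and 9.62 ± 3.15% (exact permutation p = 0.667 each). Plasma nuclei, not among the 7 classes compared, numbered 25 and 9 against 181 and 577 (exact permutation p = 0.333 for the share).

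**Figure D4:**
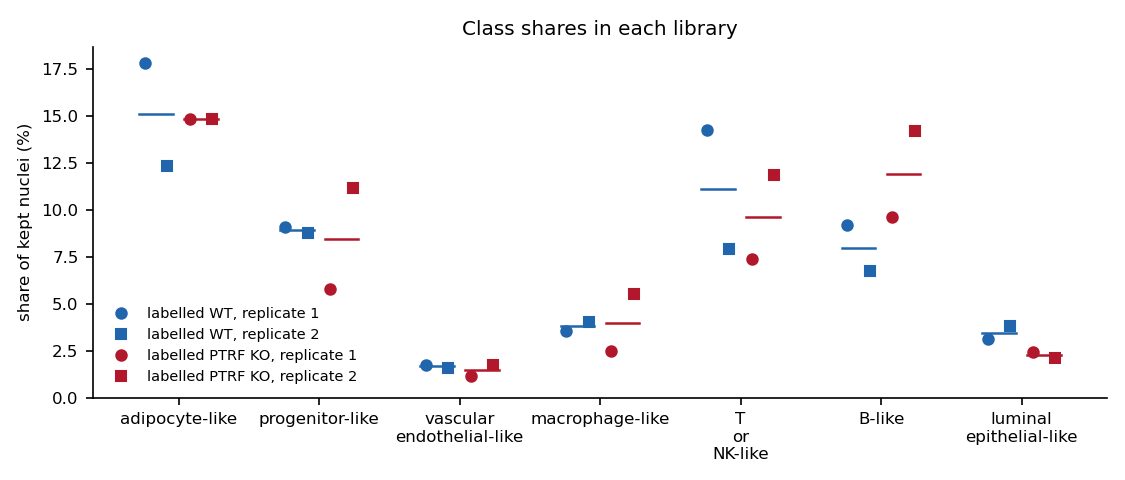
Share of nuclei in each of 7 classes, one point per library, with bars at the group means.

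Adipocytes and progenitors differed in how 16 of 16671 genes moved, 6 more upward and 10 more downward in adipocytes (17 and 16 of 33 with DESeq2 size factors). Enpp2, which encodes the lipid-signalling enzyme autotaxin, was lower in adipocytes only (-2.07 against 0.93 in progenitors; difference -2.97, SE 0.34, adjusted p = 4.85e-04). Collagen genes Col6a3 (-1.55 against 0.87; difference -2.22, adjusted p = 0.0137) and Col5a3 (0.20 against 2.13; difference -2.00, adjusted p = 0.0306) had a difference below 0 as well. The cytoskeletal gene Synpo2 (1.68 against -0.78; difference 2.40, adjusted p = 0.0107) and the macrophage growth factor gene Csf1 (1.84 against -0.75; difference 2.45, adjusted p = 0.0193) had a difference above 0. The directions are again of labels that Cavin1 contradicts. Without labelled wild type 1 edgeR called 0 genes (1194 at unadjusted p below 0.05; 33 called with DESeq2 size factors on all libraries). Without labelled knockout 2, 2 were called and neither was among the 16, and without labelled wild type 2 the count was 29.

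**Figure D5:**
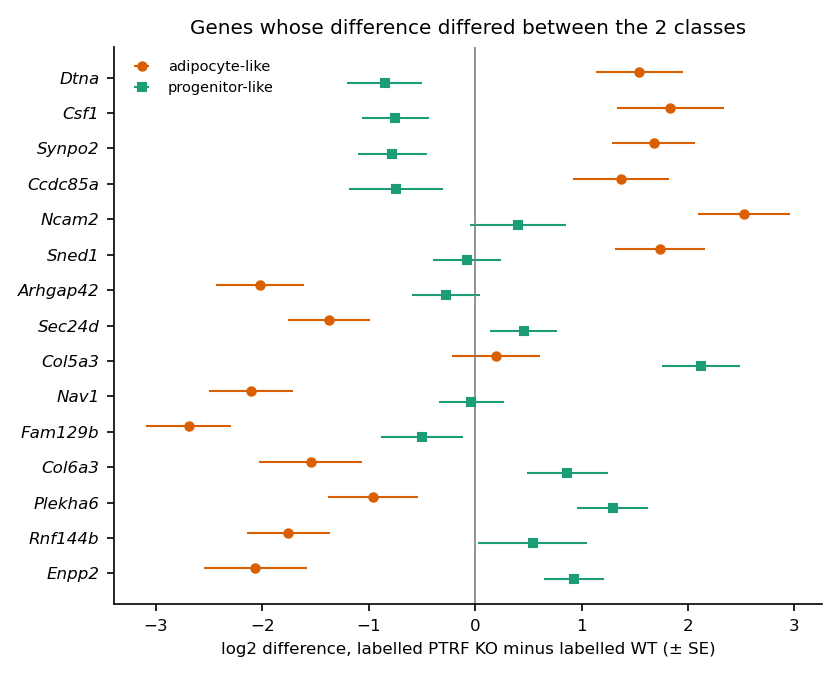
Log2 difference ± SE in adipocytes and in progenitors of 15 genes whose difference was not the same in the 2 classes.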

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

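Tests of exchanged labels, cell mix, free RNA, a strain or copy number variant, and adipocyte RNA in cluster 0 were chosen only after the result was seen.

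A test of the interaction of class and label singled out 16 genes whose difference between the labelled groups was not the same in adipocytes and progenitors. The differences, adipocyte minus progenitor on the log2 scale, were below 0 for genes including Enpp2 (-2.97), Rnf144b (-2.28), Plekha6 (-2.24), Col6a3 (-2.22), Fam129b (-2.16), Nav1 (-2.08), Col5a3 (-2.00), Sec24d (-1.92) and Arhgap42 (-1.76). They were above 0 for Dtna (2.46), Csf1 (2.45), Synpo2 (2.40), Ccdc85a (2.08), Ncam2 (2.06) and Sned1 (1.82). Enpp2, Nav1, Fam129b and Arhgap42 had log2 differences below -2 in adipocytes and between -0.50 and 0.93 in progenitors. No technical or biological explanation was tested for these genes, and Cavin1 goes against the labels that give the directions.

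Cavin1 stood low in both libraries labelled wild type and high in both labelled knockout. A different mix of cell types is argued against: with the compared classes at equal weight the log2 difference was 4.80. Exchanged labels fit: in adipocytes the highest library labelled wild type reached 4.00% of the lowest labelled knockout, and the names of all 4 files carry the other genotype. A rise of Cavin1 transcripts in knockout mice, for example from a targeted region outside the counted part, was not tested. It would not account for the near absence of Cavin1 in the libraries labelled wild type. Counts there were 20 and 2 in adipocytes and 1 and 0 in vascular endothelial nuclei. These counts and the file names argue against a rise as the only explanation.

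Gm47283, a predicted gene annotated on chromosome Y (90784738 to 90816464), was 42.4 and 28.9 CPM in the libraries labelled wild type and 2245 and 1465 in those labelled knockout. Reads moved between near-identical annotated copies are argued against: summed with its copy Gm21887 on chromosome X, the log2 difference was 5.69. Free RNA from a cell type is still open, because the lowest class held 0.350 and 0.485 of the level over all nuclei in the 2 libraries labelled knockout: both lie over the bound set against it, but the lower value by less than the spread between the libraries. A strain or copy number variant and a change in all cell types cannot be told apart, since the lowest log2 difference over the classes was 4.3 and the groups confound them. Because of its near-identical copy on chromosome X, Gm47283 is not read as particular to chromosome Y. Of other genes annotated on chromosome Y, Uty was 2.49, 6.73, 5.62 and 4.40 CPM and Ddx3y 0.859, 2.44, 3.47 and 1.01. Eif2s3y had 0 counts in every library, and Kdm5d had 2, 1, 0 and 4. With Xist at 912, 638, 714 and 1059 CPM, these values show no sex difference between the groups.

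Adipocyte transcripts were higher in cluster 0 of the group labelled knockout. A difference in depth is argued against: the highest median UMI count of cluster 0 was 1.09 times the lowest (643, 702, 697 and 686). Adipocyte RNA in these nuclei is still open. Over 12 called genes of adipocyte type the log2 difference in cluster 0 was 1.18 times that in adipocytes (median), but the SD over adipocyte markers of the level against adipocytes was 0.802 and 0.920 in the libraries labelled wild type, above the bound set, and 0.325 and 0.303 in those labelled knockout. Those markers stood at 14.2, 8.86, 17.7 and 19.2% of their adipocyte level. Adipocyte RNA was not tested in the other classes and clusters where adipocyte markers were called higher, so it is open there too.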

How the results depend on the processing

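Of the tests here, those chosen only after the result was seen were removal of the top 5% of doublet scores, analysis without cluster 0 or cluster 6, progenitors of cluster 4 only, vascular nuclei without those scored lymphatic, both list families adjusted together, and all tests of clusters compared by number. For every change given here the cause was not tested unless said.

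Genes called by edgeR over all nuclei numbered 29, and 13 with the DESeq2 Wald test, 3 with at least 1000 UMIs and 500 genes per nucleus, 4 with equal shares of the classes (limma), and 5 to 18 with a library left out, where the lone sample is assumed to vary like the other groups. Adipocytes gave 64 genes, 40 without the gene filter, 35 with classes set by marker score, and 9 to 178 with a library left out. Progenitors gave 6 genes, and 23 with DESeq2, 37 without the gene filter, 13 with the stricter nucleus filter, 3 by marker score, 10 without the top doublet scores, 3 in the largest cluster alone, and 4 to 81 with a library left out. In vascular nuclei 117 became 75 with DESeq2, 36 without the gene filter, 3 by marker score, 41 without nuclei scored lymphatic, where fewer nuclei remain by construction, and 54 to 158 with a library left out.

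In macrophages 1 gene became 3 without the gene filter, 3 to 11 with a library left out, and 0 by marker score with edgeR (61 at unadjusted p below 0.05, and DESeq2 called 1 in the main class). B, T or NK and luminal nuclei together gave 11, and 6 with DESeq2, 60 without the gene filter, 2 with the stricter nucleus filter, 4 by marker score and 8 to 437 with a library left out, of which luminal nuclei without labelled wild type 1 gave 436. Clusters compared by number gave 29, and 52 with DESeq2, 192 without the gene filter and 84 to 640 with a library left out. The interaction gave 16, and 33 with DESeq2 size factors, 83 without the gene filter, and 0 to 29 with a library left out (0 without labelled wild type 1, edgeR, 1194 at unadjusted p below 0.05).

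Gene lists called by camera numbered 12, 7 and 7 in all nuclei, adipocytes and progenitors, 0 in each with an estimated correlation and 0 in each with fry, and 6 to 14, 3 to 11 and 3 to 12 with a library left out. The largest progenitor cluster alone gave 4, with the interstitial list turned to higher, and there the other cluster's nuclei are absent by construction. List calls in the remaining classes and in the numbered clusters were not tested with a library left out.

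Pairing libraries by their number as a replicate block gave 4 genes in all nuclei, 18 in adipocytes, 22 in vascular nuclei, 3 in macrophages, 1 in B, T or NK and luminal nuclei together, and 45 in the numbered clusters. Progenitors kept 5 of 6 calls and gained 1, with Lum no longer called, and gene lists went from 12 to 11 in all nuclei and stayed at 7 in adipocytes and in progenitors. No source states that the numbers pair. The difference of replicate 1 minus replicate 2 within a label was correlated over genes between the 2 labels. This correlation was below 0 in every class (-0.611 in all nuclei, -0.402 in adipocytes, -0.294 in progenitors). The lost calls therefore say nothing on the size of an effect. Paired shares differed by -3.01 and 2.50 percentage points for adipocytes, -3.31 and 2.40 for progenitors, -0.591 and 0.162 for vascular nuclei, -6.86 and 3.90 for T or NK, 0.403 and 7.43 for B and -0.695 and -1.68 for luminal nuclei.

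Share differences also moved by more than the spread between replicates in other settings: adipocytes differed by 8.06 points and vascular nuclei by 0.282 by marker score, and T or NK by 4.17, B by 6.74 and luminal by -2.43 points with the stricter nucleus filter. Cavin1 stayed called in every alternative, with log2 differences of 4.63 to 5.81 in all nuclei and 4.68 to 6.24 in adipocytes.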

Other observations

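The test of glucocorticoid-responsive genes was planned before its result was seen, on a list made after the called genes were known, and the naming of Ddit4 and of the genes on chromosome 5 was chosen after their values were seen.

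In adipocytes, several genes that glucocorticoids induce fell in the group labelled knockout, the group rich in Cavin1. Mt2 (log2 -3.56), Mt1 (-2.72), Fkbp5 (-2.55), Pdk4 (-1.66) and Ddit4 (-2.80, SE 0.63, adjusted p = 0.0226), which encodes an inhibitor of growth signalling, were called, and Klf9 (-0.72) and Errfi1 (-1.15) were below 0 without a call. A lower glucocorticoid response was tested on the 12 list members with no call: the median was -0.60, and 9 lay below 0. Angptl4 (0.76), Klf15 (0.15) and Per1 (0.02) lay above 0, and Tsc22d3 was near it (-0.31). Fry (0.413) and camera with an estimated correlation (0.204) did not call them, and camera with the preset did (8.94e-05), so whether uncalled members take part cannot be told apart from their moving together.

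Plasma nuclei were found mostly in the libraries labelled knockout, at 181 and 577 nuclei against 25 and 9. Their cluster is led by Igha and Jchain, with the IgG genes Ighg3 and Ighg2b also among its leading genes, and nuclei were not counted by antibody type. Nuclei of cluster 12, led by the dendritic-type genes H2-M2 and Fscn1, made up 2.53 ± 0.327% in the group labelled wild type and 0.838 ± 0.0525% in that labelled knockout, and those of cluster 16, led by Cxcl13 and Lepr, 1.03 ± 0.214% and 0.451 ± 0.0478% (n = 2, exact permutation p = 0.333 each, the smallest possible). Cluster 6, led by the milk protein genes Csn2 and Lalba, held 1868 and 28 nuclei in the libraries labelled wild type and 614 and 261 in those labelled knockout.

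On chromosome 5, Speer4cos (15680710 to 15714596; log2 -2.59, SE 0.51), Gm43391 (-2.31) and Gm21847 (15516489 to 15656679; -1.89) lie next to each other and fell together over all nuclei, with Gm30613 between them (-1.39) not called. These genes resemble each other, and reads were not traced to single copies.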
